A study of Homo sapiens with 2 samples.

How the data were processed

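METTL3 HiChIP was measured in 2 libraries of IMR90 fibroblasts, 1 of control cells and 1 of cells made senescent by inducible oncogenic RAS. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was cut with MboI, and the recovered DNA was made into libraries with the transposase Tn5. Per the submitters' processing notes, the genome build was hg19 and HiC-Pro 3.1.0 was used. The loop caller, the source of the anchors, the removal of duplicate read pairs, the filters and the total number of read pairs are not given in the sources used here.

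The deposited tables had no header. Each row gave the chromosome, start and end of both anchors, a whole number, and a value between 0 and about 0.564. The authors' whole number was taken as the raw count of PETs joining the anchors, since it ran from 1 upwards with a median of 1. The last value was taken as the p-value or q-value that the authors deposited for the interaction, and which of these it is was not stated. It fell with the number of PETs and with the distance between anchors. Only pairs with at least 1 PET between 2 anchors were listed, so that the tables hold part of each library: their totals are not sequencing depths, and a pair that is not listed gives no upper limit. The anchors of the libraries had different coordinates, with 1249 identical in both, so each library appears to have its own anchor set.

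From these tables the number of interactions, PETs and anchors, the distance between anchor midpoints and the number of partners per anchor were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Anchors overlapping by at least 1 bp were treated as shared. An interaction was treated as shared when an interaction of the other library joined anchors that overlapped both of its own. The chance level of anchor overlap came from 100 random circular shifts of the anchors along each chromosome. For contacts between the same sites, the anchors of both libraries were merged where they overlapped. PETs were summed over each pair of merged anchors that held an anchor of each library and lay 5 kb to 2 Mb apart. The share of control-joined pairs that the senescent library also joined was set against unjoined pairs in the same distance class, with 20 classes per factor of 10 in distance. The plan had named shuffled partners at like distance for this chance level; these were not run, and the unjoined pairs took their place. Because shared anchors are picked by the smaller table, PETs were also compared over pairs whose anchors were each listed through another partner in both libraries. To show what the selection gives, the senescent library was compared with copies of itself thinned to the control total, over all PETs or within each autosome (100 draws each). These copies keep the senescent anchors and leave out anchor calling. Thinned evenly, they gave a PET ratio of 12.1 to 13.5 over pairs listed through other partners, close to the 12.8 of all PETs. The strongest interactions were ranked by PETs and then by the deposited significance value. The scaling by the median ratio of interactions in both libraries had a factor of 1, since 54.4% of these 1907 anchor pairs had equal PETs, and is given as values without scaling. PETs per window were summed by contact midpoint in windows of 1 Mb. Coordinates are given 1-based in hg19.

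No test between groups was possible with 1 library per group, and no p-value was computed. Shares have exact Clopper-Pearson intervals, ratios have exact conditional binomial intervals and medians have binomial order-statistic intervals, all at 95% and for counting error only. PETs that are copies of the same molecule would make these intervals too narrow. The anchor ratio was tested on simulated data for the 729 shared anchors with at least 20 PETs. Intervals excluded 1 for 64 of 100 anchors lowered 4-fold in the senescent library, for 100 of 100 lowered 16-fold, and for 4 of 442 unchanged anchors with PETs in both libraries, out of 529 unchanged anchors simulated. The simulation left out the picking of anchors by the smaller table. Its rates therefore cover counting error and do not carry over to the anchors as listed.

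The regions named follow a rule written before the data were examined, as were the comparisons of interactions, PETs, spans, shared anchors, shared interactions and most-connected anchors. The comparisons by chromosome, by window, of anchor width and of PETs between shared anchors, with the pairs listed through other partners, were added after the data were seen. The rule takes the 5 interactions with the most PETs and the 3 with the longest span in each library. Its parts on promoters and gene lists were to be replaced, without an annotation, by the 10 anchors with the highest and the 10 with the lowest ratio of PETs per 100000 deposited PETs. That replacement stated no filter; the limits of the promoter part (listed in both libraries, at least 20 PETs in sum, an interval excluding 1) were carried over to the anchors later. Under them only 1 anchor was among the highest. The most-connected anchors, the fullest windows and the chromosomes were chosen for naming after their values were seen. Of the senescent interactions with the most PETs, the one on the mitochondrial chromosome is given apart. Windows, anchor ratios and chromosome shares leave out chromosome X.

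An hg19 gene annotation was not used here. The planned promoter classes and lists of secretory, cell-cycle, fibroblast and other genes were therefore not analysed here, and contacts are named by position. The number of protein-coding genes per chromosome came from a RefSeq table of another build, GRCh38.p14, and was divided by the position of the last senescent anchor on the chromosome. Alternatives were other minimum PET numbers, stricter values of the deposited significance column, thinning of the senescent PETs, other rules for shared anchors, weighting by PETs and other scalings.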

Results

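The libraries were HiChIP libraries for METTL3, the catalytic subunit of the RNA adenosine methyltransferase complex, from IMR90 cells, a line of human embryonic lung fibroblasts. HiChIP ligates DNA ends that lie close together in the nucleus and then enriches, by immunoprecipitation, the ligated fragments bound by the protein of interest. The comparison was between 1 library of control cells and 1 library of cells driven into senescence by an inducible fusion of the estrogen receptor with oncogenic H-RAS. It addresses how the chromatin contacts held at METTL3-bound sites are arranged in each state. The files listed pairs of genomic intervals, called anchors here, with the number of paired-end tags (PETs) that joined them. The control library held 14373 PETs in 12221 interactions, and the senescent library held 184165 PETs in 150390 interactions. With 1 library per group, no difference below has a replicate check, and all intervals are 95% intervals that cover counting error only.

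The senescent library listed many more contacts than the control library. Whether the listed anchors were bound by METTL3 was not tested. Its interactions were 12.3 times as many, its PETs 12.8 times and its anchors 6.16 times (72944 against 11845). The anchors of the senescent library covered 269.02 Mb, against 36.4 Mb in the control library. They were also wider, with a median of 2927 bp against 2708 bp, and 1758 of them (2.41%) exceeded 10 kb, against 32 (0.270%) in the control library. An anchor had a median of 3 partners in the senescent library and 2 in the control library. Interactions rested on few PETs in both libraries, with a mean of 1.18 in the control library and 1.22 in the senescent library: the median was 1, and 13.3% of control interactions (12.7 to 13.9%, exact Clopper-Pearson interval) and 14.4% of senescent interactions (14.2 to 14.5%) had at least 2. When the senescent PETs were thinned to the control total, 14030 interactions were left on average over 100 draws, and 2.21% of them had at least 2 PETs.

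Most sites of the control library were also sites of the senescent library, but not the other way around. Of the control anchors, 8269 (69.8%, 69.0 to 70.6%) overlapped a senescent anchor by at least 1 bp, against 15.5% on average when the control anchors were shifted along their chromosomes. Only 8051 senescent anchors (11.04%, 10.8 to 11.3%) overlapped a control anchor, against 2.55% after shifting, which left 64893 anchors listed for the senescent library alone. Of the senescent interactions, 113796 (75.7%) had both ends at such anchors and 30109 (20.02%) had 1 end there. Interactions between shared anchors numbered 6617 in the control library and 6456 in the senescent library.

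Between the anchors that both libraries listed, the PETs were closer in number than over all interactions. Over 81735 pairs of shared anchors that lay 5 kb to 2 Mb apart, the control library had 7899 PETs and the senescent library 9236, an unscaled ratio of 1.17 (1.13 to 1.21, exact conditional binomial interval). The ratio was 1.31 (1.23 to 1.39) for anchors under 20 kb apart and 1.24 (1.18 to 1.30) for 20 to 100 kb. It was 1.02 (0.960 to 1.08) for 100 to 500 kb and 1.02 (0.926 to 1.12) from 500 kb to 2 Mb. The ratio depended on which anchors were compared: where the senescent anchors were together no wider than the control anchors it was 0.492 over all distances. Counting anchors within 5 kb of each other as shared gave 1.69. Shared anchors are those that the smaller table lists: when the senescent library was set against its own copy thinned to the control total, the same ratio was 3.58 (3.52 to 3.63 over 100 draws) and not the 12.8 of all PETs. Over pairs whose anchors were each listed through another partner in both libraries, the control library had 5308 PETs and the senescent library 7858, a ratio of 1.48 (1.43 to 1.53). The ratio was then 1.505 (1.44 to 1.57) under 100 kb and 1.44 (1.36 to 1.53) beyond. Of 6458 anchor pairs joined in the control library, 1907 (29.5%, 28.4 to 30.7%) were also joined in the senescent library. Of pairs of shared anchors at like distance that were not joined in the control library, 24.5% were joined in the senescent library. Pooled over distances, the first share was 1.20 times the second. By wider distance classes, the shares of joined and unjoined pairs were 60.05% and 53.9% under 20 kb, and 36.3% and 24.9% for 20 to 100 kb. They were 13.9% and 8.57% for 100 to 500 kb, and 3.83% and 1.66% from 500 kb to 2 Mb. Anchors of unjoined pairs were each listed through another control partner, which joined pairs did not need. The value of 1.20 therefore does not measure how far contacts were kept.

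**Figure D1:**
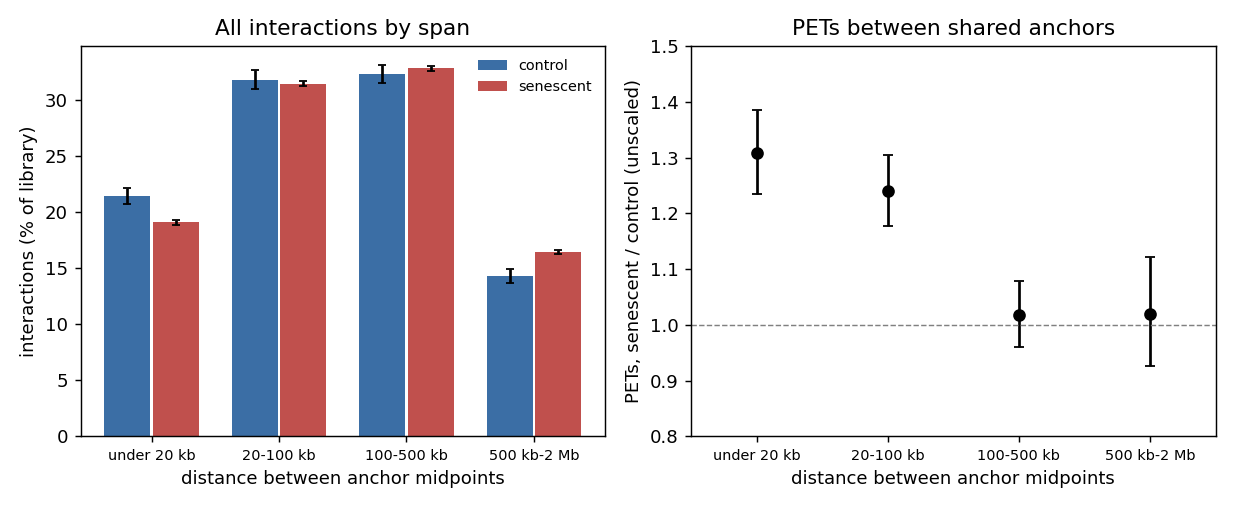
Left, the percentage of each library's interactions (y axis) in 4 classes of distance between anchor midpoints (x axis), for the control library (blue) and the senescent library (red), with exact 95% counting intervals as bars. Right, the unscaled ratio of senescent to control PETs between anchors that both libraries list (points, 95% counting intervals, axis from 0.8), which was 1.31 under 20 kb and 1.02 beyond 100 kb.

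The contacts of the senescent library lay on gene-dense chromosomes far more than those of the control library. Chromosome 19, with the most protein-coding genes per Mb of the 22 autosomes (24.6), held 8274 senescent interactions (5.54% of the autosomal ones) and 39 control interactions (0.320%), a ratio of shares of 17.3 (12.7 to 24.4). The shares were also higher in the senescent library on chromosome 22 (5.85 times, 4.52 to 7.70), chromosome 16 (5.11 times, 4.23 to 6.23), chromosome 20 (3.12 times, 2.62 to 3.76) and chromosome 17 (2.88 times, 2.56 to 3.25). Not all gene-dense chromosomes followed: chromosome 11 (9.66 genes per Mb) had a ratio of 1.04 (0.960 to 1.13), chromosome 1 (8.28 genes per Mb) 1.18 (1.11 to 1.26) and chromosome 12 (7.65 genes per Mb) 0.901 (0.834 to 0.974). Chromosome 21, with 4.97 genes per Mb, had a ratio of 1.41 (1.18 to 1.71). The shares were lower on chromosome 4, with a ratio of 0.427 (0.396 to 0.460), chromosome 6 (0.570, 0.535 to 0.608) and chromosome 13 (0.603, 0.541 to 0.673). Across the 22 autosomes, which are not replicates, the log2 ratio of shares followed the number of protein-coding genes per Mb with Pearson's r = 0.83 and Spearman's rho = 0.68. Without chromosomes 17 and 19, which lie farthest from the median gene density, r was 0.70 and rho 0.59.

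The anchors differed by chromosome as well. Relative to an even spread over the length of the autosomes, anchors on chromosome 19 were 2.04 times as frequent in the senescent library and 0.256 times (0.196 to 0.328) in the control library. Anchor density followed gene density across the 22 autosomes in the senescent library (r = 0.92, rho = 0.93) and not in the control library (r = -0.51, rho = -0.29). Between shared anchors, chromosome 19 held 32 control and 28 senescent interactions, a ratio of shares of 0.912 (0.529 to 1.56). The senescent library against its own copies, thinned to the control total of each autosome, gave 0.574 there (0.471 to 0.709 over 100 draws). Because those copies are unequal by chromosome, a ratio near or under 1 does not show equal contacts. For the interactions between shared anchors r was -0.13 and rho -0.16. The intervals of the other chromosomes held 1 except for chromosome 22 (38 control and 18 senescent interactions, 0.494, 0.265 to 0.887), chromosome 4 (0.839, 0.716 to 0.983) and chromosome 1 (1.12, 1.01 to 1.24). Over pairs whose anchors were each listed through another partner, rho was 0.225, and chromosome 19 held 2 control and 37 senescent PETs, an unscaled ratio of 18.5 (4.77 to 158). It is a ratio of PETs and not of shares, and over all such pairs the unscaled ratio was 1.48.

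**Figure D2:**
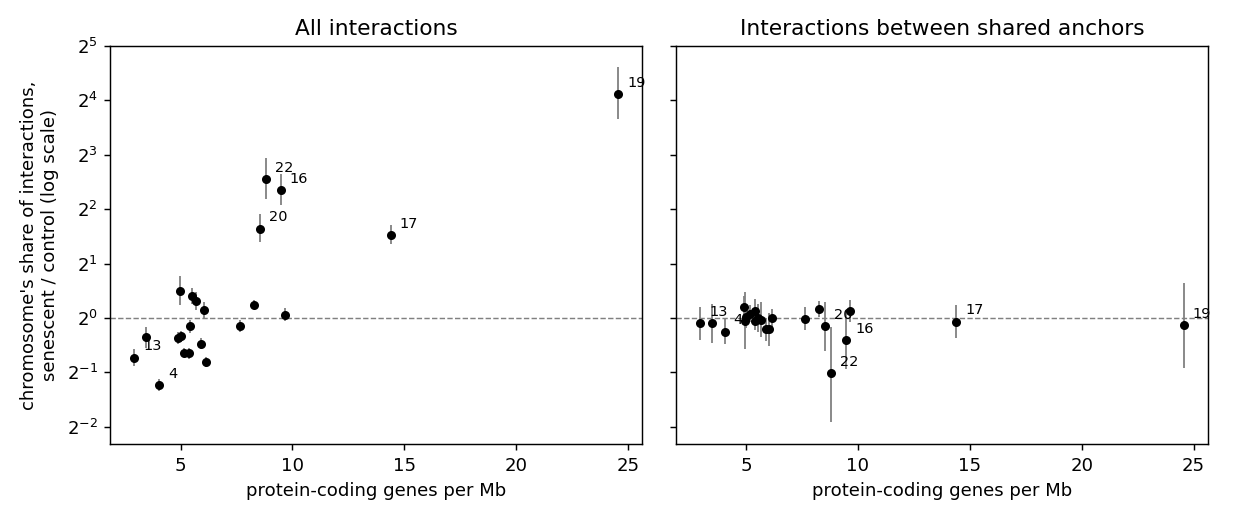
Ratio of each autosome's share of interactions, senescent over control (y axis, log scale), against protein-coding genes per Mb (x axis), for all interactions (left) and for interactions between anchors that both libraries list (right). Points are chromosomes, some with their number, and bars are 95% counting intervals. On the left chromosome 19 stands at 17.3, and on the right at 0.912. Senescent copies thinned to be unequal by chromosome gave 0.574 for the right-hand value, so it does not show equal contacts.

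The regions with the most contacts differed for the most part between the libraries. In the senescent library these were 1-Mb windows on chromosome 17 at 79 to 80 Mb (665 PETs), chromosome 19 at 2 to 3 Mb (629 PETs) and 1 to 2 Mb (585 PETs), chromosome 1 at 32 to 33 Mb (590 PETs) and chromosome 19 at 18 to 19 Mb (562 PETs). The control library listed 1 PET in the window on chromosome 1 and none in the other 4. In the control library the fullest windows were on chromosome 6 at 56 to 57 Mb (138 PETs), chromosome 5 at 52 to 53 Mb (111 PETs), chromosome 7 at 116 to 117 Mb (99 PETs) and chromosome 2 at 238 to 239 Mb (96 PETs). The senescent library held 85, 167, 121 and 466 PETs there. The window on chromosome 2 was thus full in both libraries: chromosome 19 at 3 to 4 Mb, among the fullest senescent windows, also held 466 senescent PETs. Per 100000 deposited PETs, the window on chromosome 6 held 960.1 PETs in the control library and 46.2 in the senescent library, and that on chromosome 5 held 772 and 90.7. Windows on chromosome 2 at 189 to 190 Mb and 190 to 191 Mb held fewer PETs in the senescent library even without scaling: 84 and 75 in the control library, against 40 and 34. The window on chromosome 8 at 106 to 107 Mb held 71 and 26. Over all autosomes, 770 windows had contacts in the senescent library and none in the control library, 34 had the reverse, and 1578 had contacts in both.

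Of 729 shared anchors with at least 20 PETs over both libraries, 1 had a scaled ratio whose interval lay above 1, 287 had an interval below 1, and 441 had an interval that held 1, with each library scaled to its deposited PETs. The median log2 ratio was -1.30 over these anchors and -2.46 over all 7927 shared anchors. Scaled instead to the PETs between shared anchors, the median was 2.15, and 505 intervals lay above 1 and 11 below. That factor counts only PETs between shared anchors, whereas each anchor's PETs count all its partners. The mismatch raises these ratios, since PETs with 1 shared end numbered 37229 in the senescent library and 4792 in the control library. Without scaling the median was 2.38, with 542 above and 5 below, so the direction for most anchors was set by the scaling. The anchor on chromosome 9 at 130315031 to 130343452 had 1 PET in the control library and 82 in the senescent library. Scaled to deposited PETs the ratio was 6.40 (1.12 to 256), with a log2 ratio 3.98 above the median of the 729 anchors. Its interval also lay above 1 when scaled to the PETs between shared anchors and without scaling. With shared partners alone this anchor had 1 control PET and 24 senescent PETs. The 10 anchors with the lowest ratios were 26.4 to 122 times higher in the control library per deposited PET, with log2 ratios relative to that median of -5.63 to -3.42. Scaled to the PETs between shared anchors they were 2.41 to 11.1 times higher in the control library, and without scaling 2.06 to 9.5 times. With shared partners alone, the PETs of these 10 anchors summed to 165 in the control library and 51 in the senescent library. Without scaling the intervals of 5 of the 10 held 1: the anchors with 16 against 6, 15 against 6, 16 against 7, 22 against 10 and 17 against 8 PETs. On chromosome 6, the anchor at 132379201 to 132386548 had 19 control PETs and 2 senescent PETs. Further along the same list stood 3 anchors of chromosome 6 between 56512722 and 56618413, with 20, 15 and 22 control PETs against 5, 6 and 6. The anchor on chromosome 12 at 80980464 to 80988831 had 19 and 5 PETs, and that on chromosome 11 at 121996683 to 122001434 had 16 and 6. On chromosome 5, anchors at 52148055 to 52156710 and 52309639 to 52321082 had 17 and 33 control PETs against 8 and 16. The others were on chromosome 2 at 36711538 to 36717358 (16 and 7 PETs) and on chromosome 6 at 16736005 to 16746332 (22 and 10 PETs). All coordinates are in hg19.

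**Figure D3:**
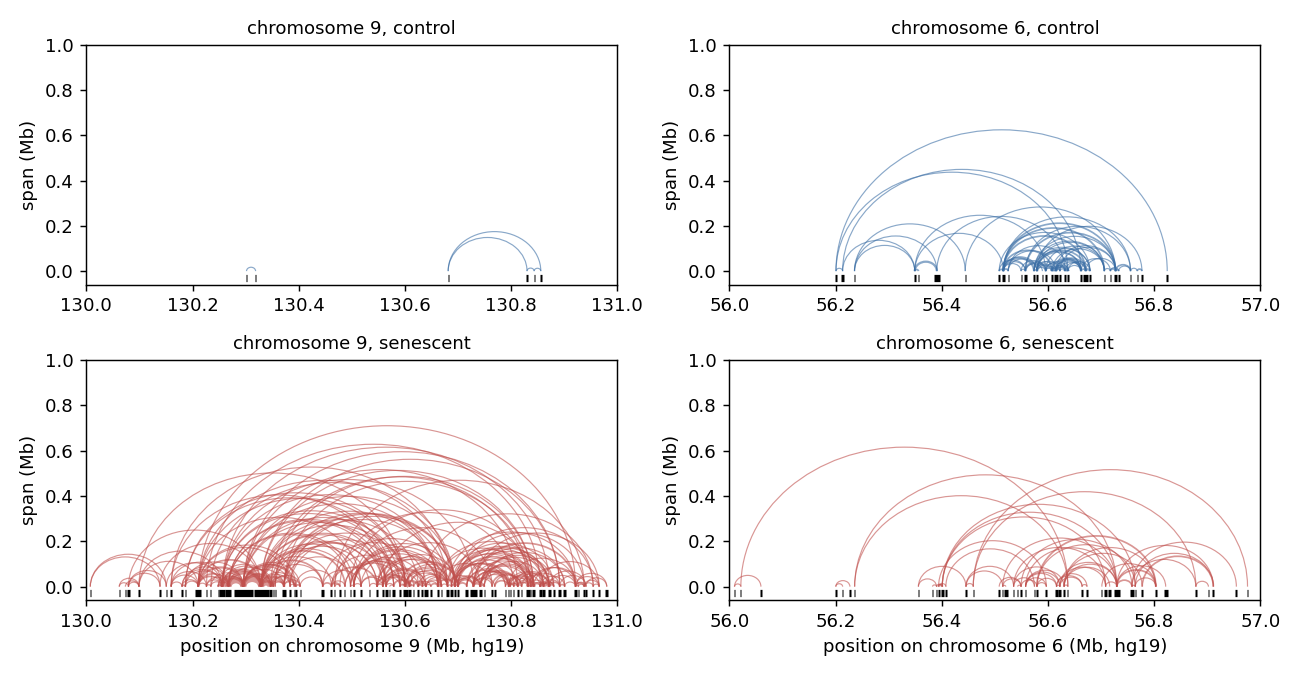
Contacts that lie within 130 to 131 Mb of chromosome 9 (left) and 56 to 57 Mb of chromosome 6 (right) in the control library (top, blue) and the senescent library (bottom, red). The x axis is the hg19 position in Mb, each arc is 1 interaction whose height is its span in Mb (y axis) and whose line is thicker with more PETs, and black marks are anchors. The window on chromosome 9 held 5 control and 307 senescent interactions, and that on chromosome 6 held 85 and 67.

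The contacts of the senescent library spanned somewhat longer distances. The median distance between anchor midpoints was 85.4 kb in the control library (81.7 to 88.7 kb) and 97.1 kb in the senescent library (95.9 to 98.2 kb), 1.14 times longer. Spans under 20 kb made up 21.5% of control interactions (20.8 to 22.2%) and 19.1% of senescent ones (18.9 to 19.3%). Spans from 500 kb to 2 Mb made up 14.3% (13.7 to 14.9%) and 16.5% (16.3 to 16.7%). Spans ran from 5001 to 1995355 bp in the control library and from 5000 bp to just under 2 Mb in the senescent library, and no interaction joined different chromosomes. Weighting by PETs, leaving out short spans and asking for at least 2 or 5 PETs gave ratios of 1.04 to 1.58. The strongest 12221 senescent interactions, ranked by PETs and then by the deposited value, had a median span of 44.1 kb, 0.517 times that of all control interactions. That ratio compares unlike sets: the strongest interactions all had at least 2 PETs, while 86.7% of control interactions had 1. Median spans with at least 2 PETs were 17.5 kb in the control library and 20.5 kb in the senescent library. With 1 PET they were 108 and 127 kb. With at least 2 PETs in both libraries the ratio was 1.17.

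Repeated contacts joined neighbouring anchors. The control interactions with the most PETs were on chromosome 5, between 52299714 to 52305441 and 52309639 to 52316574, and on chromosome 20, between 9387551 to 9392806 and 9396949 to 9400039, with 8 PETs each. The next were on chromosome 5 from 14166508, chromosome 4 from 160201867 and chromosome 2 from 238187319, with 7 PETs each and spans of 14.1, 14.6 and 9.98 kb. In the senescent library the nuclear interaction with the most PETs was on chromosome 9, between 130277751 to 130313577 and 130315031 to 130343452, with 22 PETs. It was followed by chromosome 10, between 80849008 to 80877633 and 80883356 to 80924629 (20 PETs), chromosome 14 from 96697974 to 96743147 (19 PETs) and chromosome 1 from 16463533 to 16484615 (18 PETs). The longest spans were single PETs in each library. In the control library they were on chromosome 5 from 135338744 to 137338003, chromosome 18 from 37525576 to 39521287 and chromosome 4 from 78841744 to 80837669. In the senescent library they were on chromosome 22 from 21554375 to 23564228, chromosome 3 from 50238029 to 52239773 and chromosome 17 from 6382122 to 8385789. Of the control interactions, 2028 (16.6%, 15.9 to 17.3%) had a senescent counterpart at both anchors. Those had a median span of 24.7 kb and at least 2 PETs in 25.05% of cases, against 112 kb and 10.96% for control interactions without a counterpart.

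The anchors with the most partners were wide sites in the senescent library and mostly so in the control library. Those named below were 13.5 to 28.6 kb wide in the senescent library (median anchor 2927 bp) and 8.04 to 11.6 kb in the control library (2708 bp). The next senescent anchor in rank, on chromosome 11 at 65654167 to 65690440 (36 partners), was 36.3 kb wide. The next control anchor, on chromosome 7 at 115897804 to 115901716 (13 partners), was only 3.91 kb wide. In the senescent library the first was on chromosome 10 at 80849008 to 80877633, with 38 partners and none listed in the control library. The next were chromosome 5 at 148849195 to 148871270, chromosome 12 at 125214132 to 125233612 and chromosome 8 at 128745464 to 128758946, each with 37 partners against 3, 0 and 4 control interactions. In the control library the first was on chromosome 7 at 115905447 to 115913863, with 15 partners against 12 senescent interactions. It was followed by chromosome 2 at 238187319 to 238195362, chromosome 11 at 121950928 to 121961166 and chromosome 3 at 149289586 to 149301228, with 14 partners each against 18, 7 and 13. The top 1% of anchors took part in 8.21% of control interactions (7.73 to 8.71%) and 9.20% of senescent interactions (9.06 to 9.35%).

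The deposited significance values of single-PET contacts lay at different levels in the libraries. Every single-PET contact over 500 kb had a value of 0.0105 in the control library (1729 contacts) and 0.00394 in the senescent library (24472 contacts). A threshold of 0.01 fell between these levels, and 302 control and 77699 senescent interactions lay below it, of which 1 and 70956 had a single PET. Below 0.001 there were 167 control and 3979 senescent interactions, and below 1e-05 there were 20 and 545.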

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

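The test of single-PET contacts and the ratio under 100 kb that tests anchor width were set out before their results were seen; the other tests in this part, and the reading of that ratio against the pairs beyond 100 kb, were chosen after their results were seen.

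A signal outside the nuclear contacts stood out. The mitochondrial chromosome had 1 interaction in the senescent library, between 3694 to 6904 and 11923 to 16571, with 166 PETs. It was the interaction with the most PETs of either library, and the control library listed none on that chromosome, where the senescent share would give 12.955 PETs.

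The senescent library listed 12.3 times as many interactions. More PETs at every anchor pair, as in a deeper library with the same anchors, are argued against as the whole cause: between anchors listed through other partners the PET ratio was 1.48 (1.43 to 1.53), where thinned copies of the senescent library gave 12.1 to 13.5. The 95.7% of senescent interactions that touched an anchor with no control counterpart restate where the excess lies and test no cause of it. Depth acting through the calling of anchors and the senescent state cannot be told apart, because there was 1 library per group and neither the anchor calls nor the read depth is known.

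The senescent contacts lay on gene-dense chromosomes. Single-PET contacts as the only carriers of this pattern are argued against by a rank correlation of 0.71 among interactions with at least 2 PETs. Whether the contacts arose by chance is not decided by it. The chromosome shares of the anchors alone gave 0.70, so chance contacts between them could give a like value. Control chromosome 19 held only 6 interactions with at least 2 PETs. An even background as the whole of the control library is argued against by its anchors on chromosome 19, picked as the lowest of the 22 autosomes, at 0.256 of an even spread with an upper bound of 0.328; chromosomes 22, 16 and 20 stood at 0.324, 0.400 and 0.654, and chromosomes 17, 11 and 1 at 0.937, 1.03 and 1.13. Unequal contact numbers between the same anchors cannot be told apart from equal ones: the rank correlation of -0.16 between shared anchors lies where copies thinned to be unequal by chromosome also lie (-0.289 to 0.069), and that of 0.225 between anchors listed through other partners lies below such copies (0.465 to 0.793) and within evenly thinned ones (-0.551 to 0.471), while chromosome 19 alone had an unscaled PET ratio of 18.5 (2 against 37 PETs) there. A partial background, the recovery of GC-rich DNA and a different set of METTL3 sites in the senescent state also remain open.

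Between shared anchors, the senescent library had more PETs than the control library at distances under 100 kb (ratio 1.27, 1.22 to 1.32), and about as many beyond (1.02, 0.968 to 1.07), a near ratio of 1.25 times the far ratio (1.17 to 1.33). Picking anchors by the smaller table is a candidate explanation: the senescent library against its own thinned copies gave 1.26 (1.21 to 1.31), and over pairs listed through other partners the observed value was 1.04 (0.972 to 1.12). Those copies are unlike the control library, with a PET ratio of 3.58 between shared anchors where 1.17 was observed. The like value of 1.26 therefore does not show that this picking gave the near excess. Wider senescent anchors cannot be told apart from this picking: where they were no wider, the ratio under 100 kb was 0.501, which meets the criterion written beforehand, a ratio close to or under 1, but the ratio beyond 100 kb was 0.479, so that both fell together and the criterion does not bear on the near excess. The near ratio over the far ratio was 1.046 (0.903 to 1.21) there and 1.27 (1.18 to 1.36) where they were wider. The second value was 1.21 times the first (1.03 to 1.43). These are normal intervals on the log scale for counting error only, and width may itself follow the counts. A difference in short contacts in the senescent state stays untested.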

How the results depend on the processing

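The alternatives for gene density, PET ratio, anchor scaling, repeat contacts, spans with at least 2 PETs and the value 0.011 were chosen after seeing the data. The ratio of 12.3 in the number of interactions was 17.7 for at least 3 PETs and 37.6 for at least 5 PETs. It was 257 for a deposited value below 0.01, 23.8 below 0.001, 27.25 below 1e-05 and 21.6 below 0.011. After thinning to the control total of PETs it was 1.148. Thinning gives at most 1 interaction per PET drawn, and 85.6% of senescent interactions had 1 PET. The thinned value is therefore set mainly by the PET totals and is no check of the excess. At least 10 PETs left no control interaction and gave no ratio. The percentage with at least 2 PETs, 1.07 points higher in the senescent library, was -11.1 points after thinning. Thinning lowers this percentage by itself, because PETs of the same interaction are seldom drawn together, and no other cause was tested. The log2 ratio of median spans (0.19) was 0.060 weighted by PETs, 0.22 for at least 2 PETs and 0.66 for at least 5 PETs. It was 0.10 for spans of at least 20 kb and -0.95 for the strongest senescent interactions. The last value sets senescent interactions of at least 2 PETs against control interactions that mostly had 1 PET, and such contacts differ in span within each library. The cause of the other differences was not tested. Shared control interactions (16.6%) were 29.4% with anchors within 5 kb, 15.7% with an overlap of at least 0.5 of the shorter anchor, 9.38% for at least 5 PETs and 4.09% for the strongest senescent interactions. Shared control anchors (69.8%) were 79.97% within 5 kb and 67.8% by the stricter overlap. The excess at the top 1% of anchors (0.995 points) was 3.27 for at least 5 PETs and 2.16 for the strongest interactions. The rank correlation with gene density reversed to -0.16 between shared anchors, was 0.225 between anchors listed through other partners and kept its sign in the other alternatives run (0.59 to 0.71). The PET ratio between shared anchors (1.17) was 1.69 within 5 kb, 1.12 for pairs at least 20 kb apart, 1.48 between anchors listed through other partners and 0.492 where senescent anchors were no wider; the cause of these differences was not tested. Intervals above and below 1 (1 and 287 anchors) were 505 and 11 when scaled to PETs between shared anchors, although the anchor PETs counted all partners. They were 542 and 5 without scaling (the median ratio of interactions in both was 1). Of the 10 anchors named as lowest, 5 had an interval holding 1 without scaling and none when scaled to PETs between shared anchors. Other promoter windows, PET minimums and scalings for promoter classes and gene lists were not run, and leaving out a replicate was not possible. No paired analysis was possible because each group had 1 library. With 32 control interactions of at least 5 PETs, 3 of them shared, the small number leaves a wide interval (1.98 to 25.02%).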

Other observations

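The values in this part were chosen after the results were seen. The widest sites of the senescent library were long stretches. The first was on chromosome 7 at 27134513 to 27197775 (63.3 kb), with 29 partners and 57 PETs, where the control library had 6 interactions. It was followed by chromosome 16 at 2128633 to 2181288 (52.7 kb, 16 partners), with none listed in the control library. Next came chromosome 17 at 48249557 to 48291503 (41.9 kb), with 27 partners against 1 control interaction. The widest control anchor, on chromosome 9 at 21674088 to 21691482 (17.4 kb), had 8 partners and 12 PETs, against 8 interactions and 9 PETs in the senescent library. The control anchors on chromosome 12 at 78332197 to 78344663 (12.5 kb, 10 partners) and chromosome 3 at 136666096 to 136678513 (12.4 kb, 2 partners) had no senescent interaction.

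Of the anchors listed for the senescent library alone, 9.64% lay within 10 kb of a control anchor and 41.8% within 100 kb. Possible anchor pairs 5 kb to 2 Mb apart numbered 180526 in the control library and 5670792 in the senescent library, and 6.77% and 2.65% of them were joined. Every anchor is listed through a contact, so this percentage tends to be higher where fewer anchors are listed. It does not show that control anchors were more densely joined: they had a mean of 2.06 partners, against 4.12 in the senescent library.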
